A study of Solanum lycopersicum with 12 samples.

How the data were processed

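RNA from tomato stems was sequenced for 4 groups of 3 libraries, control and weighted stems at 6 h after the start of the treatment and at 10 days after its end. The time of the first collection follows the series' design text; the labels call the same group 6 hours post treatment. Per the labels' protocols, reads were aligned to a reference genome with HISAT and to reference genes with Bowtie2; versions, genome build, annotation and the treatment of reads that map to several genes are not given in the sources used here. Genes of near-identical copies, such as those of chlorophyll a-b binding protein 1B, potato inhibitor I and the SAUR family, may therefore share reads, and their single values are uncertain.

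The authors deposited FPKM values per library in 2 tables, 1 for each time, and each table holds all 12 libraries. The deposited tables also give the authors' log2 ratios and Q values, used as a check. The ratios also served to choose among possible readings of damaged digits in the 6 h table. Where the Q value was legible it was under 0.05 for 2988 of 2988 genes in the 6 h table and for 908 of 909 genes in the 10 day table, so the tables hold genes already selected for differing at that time. Tests over such genes pass for nearly all of them, and the Benjamini-Hochberg adjustment runs over the selected genes alone. Enrichment against the whole genome was not testable.

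In the 6 h table column separators and decimal marks were exchanged. They were restored by script. For 90 of 5346 genes the digits needed regrouping. Their reading was chosen mainly by a small spread within groups and by the authors' log2 ratios. The SDs and fold changes of these genes therefore depend on that choice. Of the regrouped genes 12 were in both tables and could be compared directly. Among the 4464 values that both tables give, 71 differed by more than 0.005 FPKM, each by a decimal zero lost after the mark. The same loss is possible in 1584 of 64152 values (2.47%) and would move none by more than 0.091 on the log2 scale. Ratios of the mean FPKM values correlated with the authors' legible log2 ratios at 0.9998 (5236 genes, 6 h) and 0.9997 (1145 genes, 10 days), with 0 opposite signs. The regrouped genes were left out of the 6 h correlation, so it does not check their reading.

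Depth per library is unknown and no counting interval is given. Values carry 2 decimals, and of low values only 38.1% (6 h) and 45.3% (10 days) lay within 0.005 FPKM of a whole multiple of the lowest value of their gene, so read counts could not be recovered. Methods that need counts had been planned for that case and were not run.

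Values were analysed as log2(FPKM + 1) for genes with at least 1 FPKM in at least 3 of the 6 libraries of the comparison, with limma 3.58.1 (linear model, empirical Bayes with trend, two-sided) in R 4.3.3. Each comparison was fitted in its own table, and the interaction in all 12 libraries over genes in both tables. An adjusted p under 0.05 (Benjamini-Hochberg) counted as called. With 3 libraries against 3, an exact permutation test cannot go below 0.1, so none was used for single genes. Gene lists were tested with camera in limma, with the preset inter-gene correlation of 0.01 and again with an estimated one, where at least 5 members were tested. The ethylene, auxin and flowering members were also adjusted over the list alone. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

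The tests, the 42 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule takes, per comparison, the 6 largest and 6 smallest log2 fold changes among called genes with a name or domain, a mean of at least 5 FPKM in the higher group and no overlap of the groups. It adds up to 3 called members of each list by absolute log2 fold change, and for the interaction the 3 largest and 3 smallest contrasts. Names and domains are those in the deposited tables, which give one for 5733 of 6120 genes; 0 identifiers matched the reference gene table used here, so no positions are given. Another 15 lists were written after the data were seen.

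Tested on simulated data of 5028 genes, the 6 h fit recovered 90.5% of 200 genes changed by 1 on the log2 scale, with 11 false calls among unchanged genes. The 10 day fit, on 1114 simulated genes, recovered 92% of 200, with 9 false calls among unchanged genes. The interaction, on 371 simulated genes, recovered 70% of 50, with 1 false call among unchanged genes. Most simulated genes were unchanged, whereas the genes tested here had been chosen for differing, so these error rates do not carry over. Alternatives were other pseudocounts (0.1 and 0.5), other filters, 3 other scalings, array weights and a robust fit. Others took the replicate number as a block or left out each library in turn. The scalings equalised library totals over the table, or used median ratios or quantiles. Each was computed over the chosen genes alone, so it can take up part of their change and is not a neutral scale.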

Results

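The data describe gene activity in the stems of tomato (Solanum lycopersicum) plants of the cultivar Ailsa Craig after a mechanical load. A wooden clamp weighing 3 g hung from the stem tip for 48 h, and plants without a clamp were the controls. Stems were taken at 6 h, while the clamp was still in place, and again 10 days after its removal. Control and weighted plants at each time gave 4 groups of 3 biological replicates, 12 RNA-seq libraries in all. The series title names ethylene, auxins, early flowering and yield, and the comparisons ask which transcripts differed between weighted and control stems at each time and whether the difference was the same at both. One table held 5346 genes for the comparison at 6 h and the other 1146 genes for the comparison at 10 days, both with FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments of the library) for all 12 libraries. Read depth is unknown, because the tables hold no counts and the low values do not resolve into single reads.

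Over the genes of the 6 h table, the first principal component held 76.3% of the variance and separated the times. The second component held 13% and separated the groups at 6 h, with control stems between -33.17 and -24.88 and weighted stems between 24.62 and 28.47. Stems at 10 days lay between -2.44 and 4.88 on that component. Across genes, log2 values of replicates within a group correlated at 0.978 or more.

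**Figure D1:**
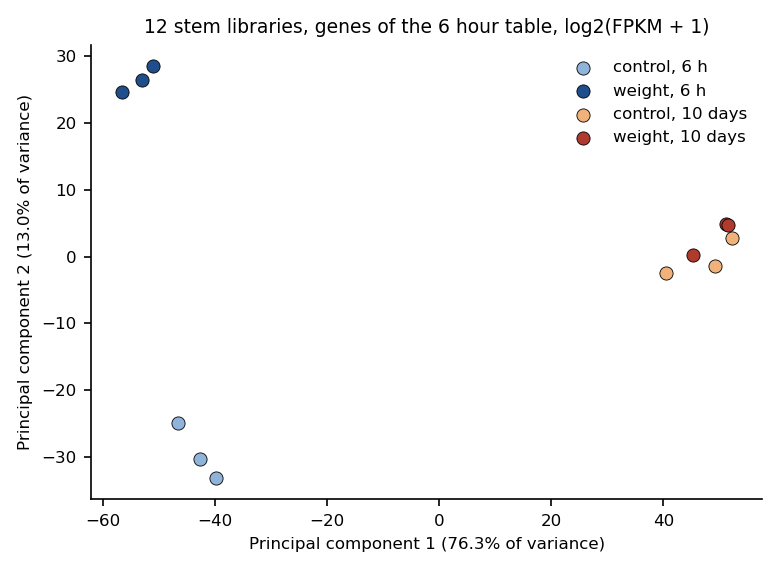
Scores of the 12 libraries on the first and second principal components of log2(FPKM + 1) over the genes of the 6 h table, 1 point per library, coloured by group. The first component (76.3% of variance) separates the times, and the second (13%) parts control from weighted stems at 6 h; the genes had been chosen for differing at 6 h.

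At 6 h the largest increase in log2 value was in an ACC oxidase gene (Solyc02g036350.3), whose product makes ethylene from its precursor ACC and which rose from 21 ± 6.20 to 403 ± 23.9 FPKM (SD, n = 3 per group; log2 fold change 4.24, SE 0.21, limma adjusted p = 8.76e-05). The transcription factor PRE4 (Solyc05g007210.2), of a helix-loop-helix family that promotes cell elongation, rose from 8.46 ± 4.11 to 127 ± 12.6 FPKM (log2 fold change 3.84). The vacuolar membrane aquaporin TIP23 (Solyc06g060760.3) rose from 15.2 ± 7.79 to 208 ± 50.9 FPKM. A dioxygenase-domain gene (Solyc02g080120.3), a J-domain gene (Solyc02g062160.1) and a Bet v 1 family gene (Solyc09g014580.3) rose by 3.74, 3.65 and 3.60 on the log2 scale. Of the genes with neither a name nor a domain, chosen after their values were seen, Solyc08g078840.3 (4.22) and Solyc01g096260.4 (3.91) rose as strongly, and Solyc06g059870.1 fell furthest in the table (-3.92, SE 1.18), with 1 weighted library at 0. Among genes with a name or domain the largest decrease was in inositol-3-phosphate synthase (Solyc04g054740.3), which catalyses the first step of inositol synthesis and went from 203 ± 22.5 to 14.8 ± 0.527 FPKM (log2 fold change -3.68). The 5 named genes after it were all of chlorophyll a-b binding proteins, with log2 fold changes from -3.23 (Solyc02g070950.1, 340 ± 70.9 to 35.2 ± 5.85 FPKM) to -2.90 (Solyc02g071000.1).

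Genes of ethylene synthesis and signalling mostly rose at 6 h. Of the 7 tested genes of ethylene synthesis 6 rose and 1 fell; besides Solyc02g036350.3, ACC oxidase 4 (Solyc07g049550.3) rose from 31.8 ± 11.9 to 100 ± 14.0 FPKM. The dioxygenase gene Solyc02g081190.4, in the list by its identifier, rose from 209 ± 17.9 to 645 ± 57.2 FPKM. The list passed camera with adjusted p = 0.0469, against adjusted p = 0.599 with an estimated correlation. This call ended without control replicate 3 (adjusted p = 0.0546) or without weighted replicate 1, 2 or 3 (0.0585, 0.0824 and 0.0638), with library totals equalised (0.0508), with array weights (0.0529), without the filter on low values (0.109) and over genes of 5 FPKM or more (0.144); over all alternatives it ran from 0.0279 to 0.144. Of 9 genes of ethylene signalling 7 rose and 2 fell, which did not pass as a list (adjusted p = 0.0743; 0.672 with an estimated correlation). Both EIN3-binding F-box genes, whose products remove the transcription factor EIN3, rose, EBF2 (Solyc07g008250.3) from 19.3 ± 3.8 to 88.7 ± 35.4 FPKM and EBF1 (Solyc12g009560.2) from 44 ± 8.96 to 122 ± 35.4 FPKM. An ethylene receptor gene (Solyc06g053710.3) rose from 13.8 ± 3.11 to 32.5 ± 5.78 FPKM. Of the 3 ethylene response factors in the list, ERF4 (Solyc05g052030.1) and ERF1 (Solyc06g065820.3) rose by 0.95 and 0.64 on the log2 scale, and a pathogenesis-related activator (Solyc06g082590.1) fell by 0.46. A wider list of AP2/ERF domain genes, written after the data were seen, went 14 up and 13 down of 27 (camera adjusted p = 0.751).

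Of the auxin lists only that of the SAUR genes passed camera at 6 h. Among the SAUR genes, small transcripts that respond early to auxin, 13 of 14 rose and 1 fell (camera adjusted p = 0.00526; adjusted p = 0.405 with an estimated correlation); the largest change was in Solyc01g110900.1, from 6.54 ± 1.42 to 45.5 ± 8.57 FPKM. Only 6 SAUR genes reached 5 FPKM in 3 libraries, and over genes at that level the list did not pass (adjusted p = 0.144, in a range of 0.00133 to 0.144). The Aux/IAA list took in 7 auxin response factors through a shared domain, and of its 18 genes 10 rose and 8 fell (adjusted p = 0.547). Divided by name, after the values were seen and with no test as a group, the 11 genes named auxin-responsive protein went 9 up and 2 down, and the 7 response factors 1 up and 6 down. The Aux/IAA gene Solyc06g053830.3 rose from 8.98 ± 0.969 to 25.4 ± 3.38 FPKM. The list of auxin response factors, which holds those 7 again, went 3 up and 6 down (adjusted p = 0.547), with Solyc01g096070.3 falling by 0.73 on the log2 scale. Of 8 genes of auxin synthesis and transport 2 rose and 6 fell (adjusted p = 0.507); the efflux carrier gene Solyc04g007690.3 rose from 5.60 ± 0.624 to 13.7 ± 1.77 FPKM, while Solyc01g068410.4 fell by 0.60. The GH3 list took in 3 beta-glucosidases named after another GH3 family, and of its 5 members 3 rose and 2 fell (adjusted p = 0.547). Its 2 genes of the auxin-conjugating family went apart, Solyc05g050280.3 rising by 1.34 and Solyc07g063850.3, chosen after its value was seen, falling by 0.79. The beta-glucosidases Solyc04g015560.4 and Solyc06g073740.3 rose by 1.355 and 1.042, and the remaining one, Solyc11g071640.3, fell by 0.895. The only member of the flowering list in this table, a bZIP gene (Solyc02g083520.2), fell by 0.65. In the ethylene, auxin and flowering lists together, all 67 tested members were called adjusted over the list alone, as over all genes tested. Of these 45 rose and 22 fell, the 3 beta-glucosidases included. Nearly all genes tested at 6 h were called (4995 of 5028), so this count does not set these lists apart.

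**Figure D2:**
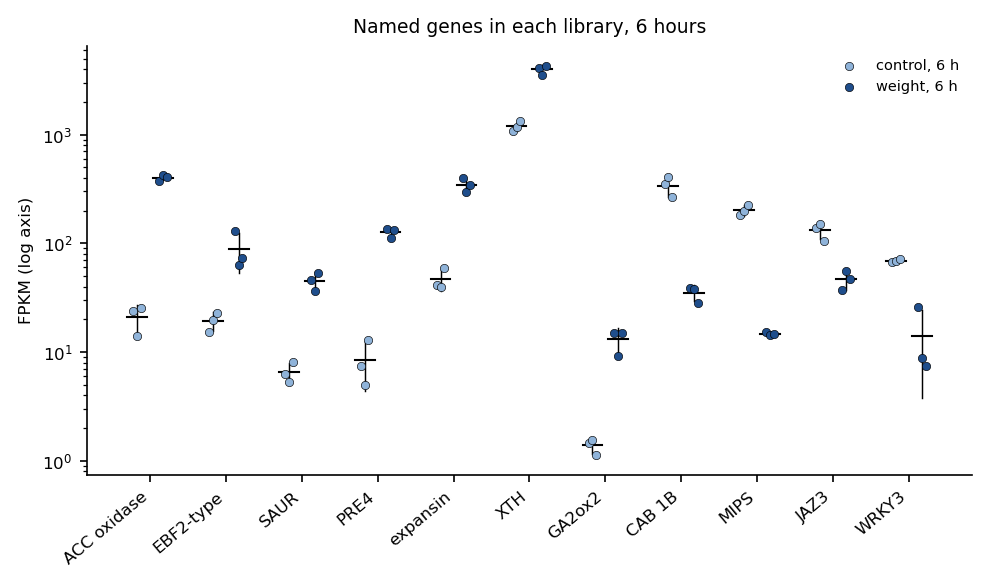
FPKM on a log axis of 11 named genes in each of the 3 control and 3 weighted libraries at 6 h, with the mean as a bar and the SD as a line. The digits of the xyloglucan endotransglucosylase/hydrolase gene (XTH) had been regrouped. ACC oxidase went from 21 to 403 FPKM and the chlorophyll a-b binding protein 1B gene from 340 to 35.2 FPKM, with no overlap of the groups; MIPS is inositol-3-phosphate synthase.

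Expansin genes, whose products loosen the wall, mostly rose at 6 h and lignin genes mostly fell, while the other wall lists went both ways. Of 14 expansin genes, 11 rose, 2 fell and 1 did not pass (camera adjusted p = 0.034; adjusted p = 0.405 with an estimated correlation). The expansin Solyc04g081870.4 rose from 46.8 ± 10.5 to 345 ± 50.3 FPKM and Solyc06g049050.3 from 5.19 ± 0.774 to 29.5 ± 11.7 FPKM. This list call ended without control replicate 3 (adjusted p = 0.0788), without weighted replicate 1, 2 or 3 (0.0585, 0.0609 and 0.0561), with array weights (0.0529) and over genes of 5 FPKM or more (0.144), in a range of 0.0282 to 0.144 over its alternatives. Xyloglucan endotransglucosylase/hydrolase genes, which cut and rejoin wall xyloglucan, went 7 up and 5 down (adjusted p = 0.463). The most abundant of those named, Solyc01g099630.4, rose from 1194 ± 122 to 3986 ± 385 FPKM. Its digits had been regrouped and it was not in the 10 day table, so these values depend on the reading chosen. Pectin-modifying genes went 17 up and 21 down (adjusted p = 0.869), with a pectinesterase (Solyc09g075330.4) rising by 2.65 and another (Solyc08g078640.3) falling by 1.98. Cellulose synthase and COBRA genes went 5 up and 7 down (adjusted p = 0.778). Of 32 lignin genes 27 fell and 5 rose (adjusted p = 0.0163; adjusted p = 0.405 with an estimated correlation), among them caffeoyl-CoA O-methyltransferase (Solyc04g063210.3, 47.0 ± 6.31 to 18.2 ± 2.79 FPKM), whereas a 4-coumarate-CoA ligase (Solyc03g025720.3) rose by 1.31. With median ratios 23 lignin genes fell. Without the filter on low values the lignin list did not pass (adjusted p = 0.0601, in a range of 0.00918 to 0.0601).

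Photosynthesis genes were lower and ribosomal protein genes higher at 6 h. Of 51 photosynthesis genes 50 fell and 1 rose, with a median log2 fold change of -0.96 (camera adjusted p = 5.08e-11; adjusted p = 0.664 with an estimated correlation). Of 83 cytosolic ribosomal protein genes 81 rose and 2 fell, with a median of 0.54 and the same adjusted p values under both settings; 40S protein S30 (Solyc12g008700.3) rose from 280 ± 44.9 to 516 ± 37.2 FPKM. Circadian clock genes went 10 up and 1 down (adjusted p = 0.0114; adjusted p = 0.405 with an estimated correlation). The cold-regulated protein 27/28 gene Solyc04g078880.3, an output of the clock, rose from 2.46 ± 0.0252 to 11.6 ± 2.61 FPKM, and an EARLY FLOWERING 4 gene (Solyc06g051680.1), part of the evening complex, from 8.63 ± 1.76 to 27.3 ± 3.58 FPKM. All 10 cell cycle genes fell (adjusted p = 0.0163; adjusted p = 0.599 with an estimated correlation), as did all 7 histone genes, which did not pass as a list (adjusted p = 0.0832). With libraries scaled by median ratios, 6 of the 10 cell cycle genes and 3 of the 7 histone genes passed limma, at medians of -0.495 instead of -0.564 and -0.323 instead of -0.399; the cell cycle list passed camera under all 16 of its alternatives.

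Of the lists that mark tissues, those of the stem surface passed at 6 h and those of vascular tissue did not. All 8 trichome genes, mostly of terpene synthesis, fell (adjusted p = 0.0114; adjusted p = 0.405 with an estimated correlation), with nerylneryl diphosphate synthase CPT2 (Solyc08g005655.1) going from 11.3 ± 0.726 to 1.76 ± 0.551 FPKM. Of 21 cuticle and epidermis genes 17 rose and 4 fell (adjusted p = 0.0276; adjusted p = 0.541 with an estimated correlation); an ECERIFERUM 1-like gene of wax synthesis (Solyc01g088400.4) rose from 4.31 ± 1.01 to 15.4 ± 0.651 FPKM. That list includes lipid transfer proteins such as Solyc03g119210.1, which rose from 455 ± 80.6 to 1388 ± 258 FPKM. The digits of this gene had been regrouped and it was not in the 10 day table, so its values depend on the reading chosen. Phloem genes went 4 up and 1 down (adjusted p = 0.32), endodermis and suberin genes 6 up and 4 down (0.712), and cambium genes 5 up and 4 down (0.778). Aquaporins went 8 up and 5 down (0.435).

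**Figure D3:**
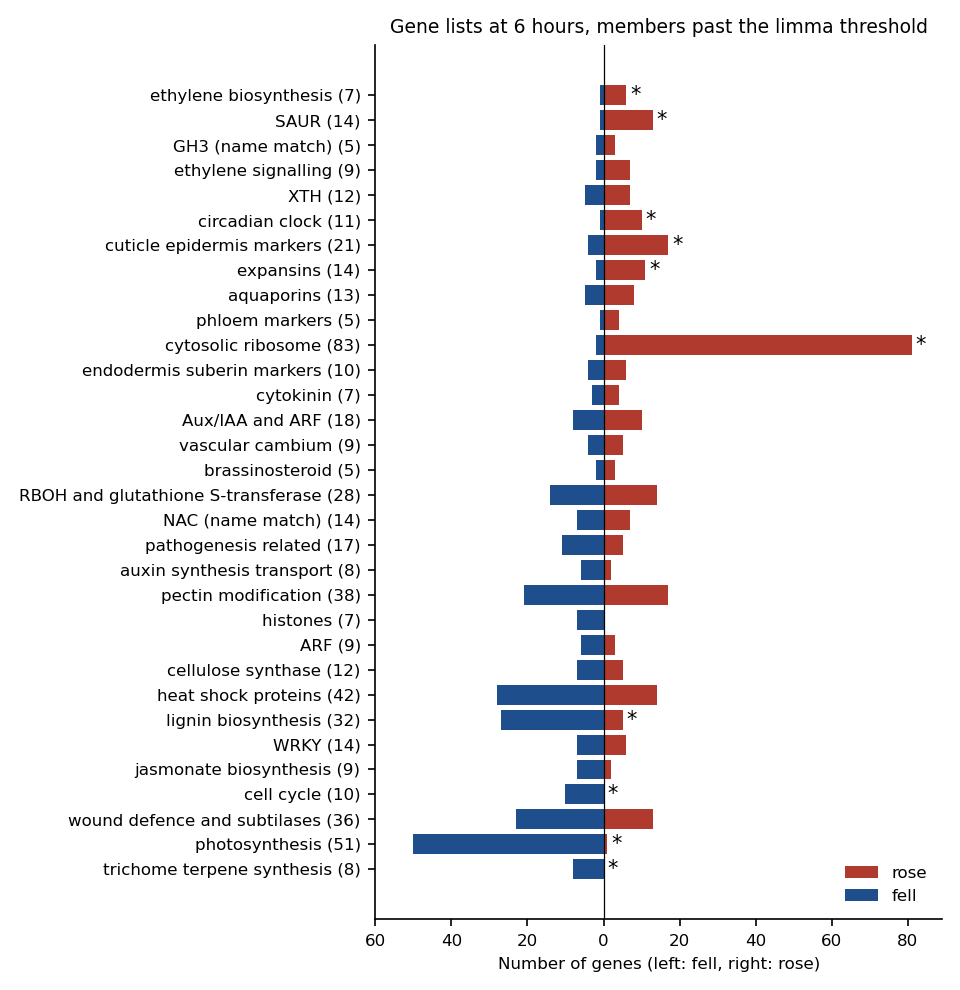
Number of members of each gene list that fell (left) and rose (right) at 6 h by limma, for the 32 lists with at least 5 tested genes; the tested number stands in brackets and an asterisk marks lists past camera with a preset correlation. Photosynthesis (50 of 51 fell) and cytosolic ribosome (81 of 83 rose) are the most one-sided of the large lists.

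Jasmonate and wound genes were mostly lower at 6 h, without passing as lists. Of 9 jasmonate synthesis genes 7 fell and 2 rose (adjusted p = 0.435), among them 12-oxophytodienoate reductase 3 (Solyc07g007870.3, 170 ± 57.3 to 75.7 ± 3.39 FPKM) and a 13S-lipoxygenase (Solyc03g122340.3, 261 ± 95.7 to 102 ± 47.1 FPKM). The latter did not pass without control replicate 1, where limma gave adjusted p = 0.051. The repressor JAZ3 (Solyc01g005440.4) fell from 132 ± 23.1 to 46.8 ± 9.15 FPKM and the regulator MYC2 (Solyc08g076930.1) by 0.59 on the log2 scale. In the wound defence list, which is made up largely of subtilisin-type proteases, 23 of 36 fell and 13 rose (adjusted p = 0.435); its 3 named members were all potato inhibitor I genes, with Solyc09g084460.3 going from 626 ± 60.6 to 201 ± 77.1 FPKM. WRKY3 (Solyc09g015770.3) fell from 69.1 ± 1.69 to 14.0 ± 10.2 FPKM and WRKY70 (Solyc03g095770.3) from 72.1 ± 6.01 to 16.3 ± 10.7 FPKM, in a family that went 6 up and 7 down.

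Single genes of other hormones changed at 6 h. Gibberellin 2-oxidase 2 (Solyc07g056670.3), which inactivates gibberellins, rose from 1.38 ± 0.223 to 13.1 ± 3.40 FPKM, and Snakin-2 (Solyc01g150176.1), of the gibberellin-regulated protein family, from 9.41 ± 2.43 to 39.2 ± 1.58 FPKM. The abscisic acid 8'-hydroxylase CYP707A1 (Solyc04g078900.3) and the dioxygenase NCED2 (Solyc08g016720.1), which break down and make abscisic acid, rose by 1.69 and 0.89. All 3 calmodulin-like genes fell, Solyc10g006740.4 most (18.3 ± 2.30 to 8.40 ± 0.604 FPKM). A wider list of EF-hand genes, written after the data were seen, went 20 up and 20 down (camera adjusted p = 0.97). Of 4 mechanosensitive channel genes 3 fell and 1 rose, the CSC1-like gene Solyc07g048110.4 rising by 0.79 and ERD4 (Solyc08g023440.3) falling by 0.65; with median ratios only 1 of the 3 falls passed limma. The MscS-type gene Solyc04g082040.3 fell by 0.40, which did not pass with library totals equalised (limma adjusted p = 0.0502), with median ratios (0.0591), without control replicate 1 or 3 (0.0694 and 0.0744) or without weighted replicate 1 or 3 (0.0856 and 0.0545).

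In all, limma on log2(FPKM + 1) called 4995 of 5028 tested genes at 6 h, 2410 higher and 2585 lower, and 722 of them changed by at least 1 on the log2 scale, 358 up and 364 down. The authors had already chosen the table's genes for differing at this time, so this count describes the table, not the share of the transcriptome that changed, and the list tests set a list against other chosen genes. Of the 32 lists tested 10 passed camera with a preset correlation and 0 with an estimated one, where 3 had an unadjusted p under 0.05. With the preset correlation as many lists passed in 6 of 10 splits of the libraries at 6 h, the real split included.

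At 10 days most tested genes of the heat shock list fell. The largest decrease was in Le-HSP17 (Solyc08g062437.1), a class II small heat shock protein, from 993 ± 685 to 170 ± 91.9 FPKM (n = 3 per group; log2 fold change -2.51, SE 0.58, limma adjusted p = 0.00524). Of the 13 tested genes in the heat shock list, which also takes in J-domain and BAG co-chaperones, 12 fell and 1 rose (camera adjusted p = 0.0127; adjusted p = 0.487 with an estimated correlation). The small heat shock protein gene Solyc03g082420.3 went from 1213 ± 728 to 346 ± 134 FPKM and Solyc04g014480.3 from 436 ± 150 to 133 ± 27.5 FPKM. A stricter list of heat shock proteins and factors, written after the data were seen, went 9 down and 2 up of 11, at a median of -1.353, and did not pass (adjusted p = 0.143, in a range of 0.0253 to 0.25; adjusted p = 0.621 with an estimated correlation). Control replicate 2 held the highest values (1768 FPKM for Solyc08g062437.1 and 2031 FPKM for Solyc03g082420.3). Without it 12 members still fell, with a median log2 fold change of -0.825 instead of -1.12 (adjusted p = 0.0265). With library totals equalised 8 fell, at a median of -0.824. After quantile normalization 10 fell and the list did not pass (adjusted p = 0.102, in a range of 0.00212 to 0.102).

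Other large decreases at 10 days were in CONSTANS 1 (Solyc02g089540.3), of a B-box family with regulators of flowering by day length, from 27.0 ± 7.29 to 6.13 ± 0.871 FPKM, and a Dof-type transcription factor gene (Solyc05g007880.4), from 24.9 ± 3.28 to 6.01 ± 0.632 FPKM. GAST1 (Solyc02g089350.3), of the gibberellin-regulated family, went from 13.4 ± 8.66 to 2.58 ± 0.391 FPKM. A phosphatase gene (Solyc06g062540.3) and a gene of the UPF0301 family (Solyc02g067050.3) fell by 1.97 and 1.91. The largest increases among genes with a name or domain were in a DUF1442 gene (Solyc06g034410.3, 3.36 ± 1.53 to 14.5 ± 4.06 FPKM) and the cysteine protease Cp5 (Solyc02g076750.3, 7.28 ± 1.77 to 24.2 ± 4.11 FPKM). An Aux/IAA gene (Solyc03g120390.3) rose from 12.9 ± 5.18 to 38.6 ± 10.5 FPKM, and a PPM-type phosphatase (Solyc06g051940.4), a LURP-one-related gene (Solyc08g081680.2) and a phospholipase A2 gene (Solyc07g014730.3) rose by 1.51, 1.49 and 1.46.

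**Figure D4:**
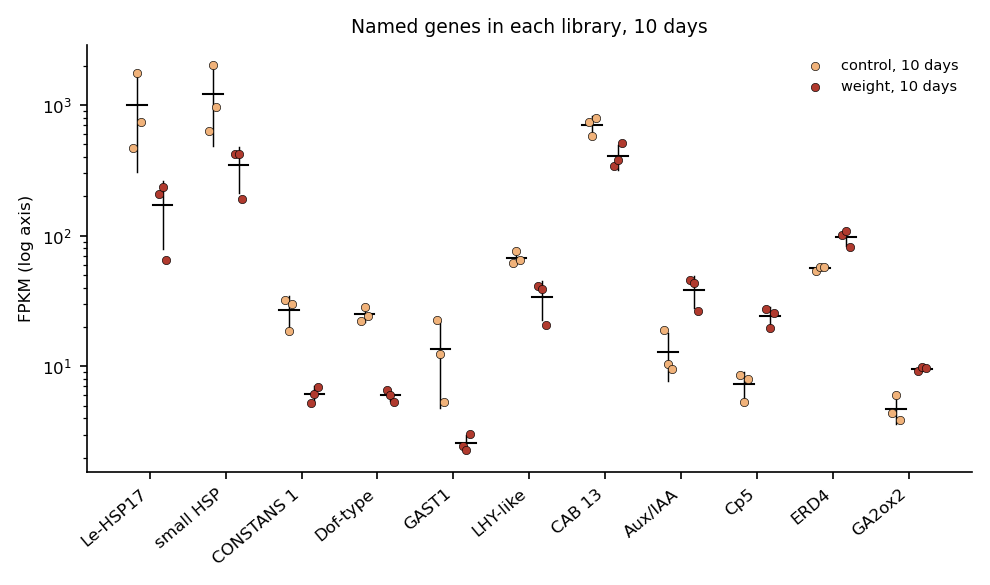
FPKM on a log axis of 11 named genes in each of the 3 control and 3 weighted libraries at 10 days, with the mean as a bar and the SD as a line. Le-HSP17 went from 993 to 170 FPKM, with 1 control library at 1768 FPKM, and CONSTANS 1 from 27.0 to 6.13 FPKM.

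All 11 photosynthesis genes tested at 10 days fell, with a median log2 fold change of -0.42 (camera adjusted p = 0.00614; adjusted p = 0.487 with an estimated correlation). Chlorophyll a-b binding protein 13 (Solyc12g011450.2) went from 709 ± 113 to 408 ± 88.8 FPKM. After quantile normalization 8 fell and the list did not pass (adjusted p = 0.102, in a range of 0.0045 to 0.102); with library totals equalised 2 fell, at a median of -0.12. The redox list held 5 glutathione S-transferase genes, detoxifying enzymes, and all 5 fell (adjusted p = 0.0452; adjusted p = 0.483 with an estimated correlation), with Solyc10g084400.2 going from 229 ± 15.6 to 127 ± 19.5 FPKM. That call ended without control replicate 1 (adjusted p = 0.0668) or 2 (0.0559), after quantile normalization (0.131), with array weights (0.0682) and with library totals equalised (0.0648), where 1 of the 5 fell at a list median of -0.22 instead of -0.511; its range was 0.0375 to 0.131. Lignin genes went 5 up and 2 down (0.339), wound defence genes 6 up and 3 down (0.339) and clock genes 3 up and 2 down (0.755). With library totals equalised the lignin genes went 5 up and 1 down and the wound defence genes 6 up and 0 down by limma. The LHY-like gene (Solyc10g005080.3), a morning gene of the clock, went from 67.9 ± 7.28 to 33.6 ± 11.1 FPKM.

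Of the ethylene, auxin and flowering lists 8 genes were tested at 10 days. All 8 were called adjusted over the list alone, as over all genes tested, 5 rising and 3 falling. Nearly all genes tested at 10 days were called (1111 of 1114), so this count does not set them apart. An ethylene receptor gene (Solyc09g089610.3) rose from 2.20 ± 0.892 to 4.79 ± 0.108 FPKM, and a GH3 auxin-conjugating gene (Solyc01g095580.3) fell from 8.89 ± 0.526 to 4.58 ± 0.172 FPKM. The auxin carrier LAX3 (Solyc11g013310.2) fell by 0.64 and an efflux carrier gene (Solyc06g059730.3) rose by 0.48. In the flowering list, a MADS-box gene (Solyc06g069430.3) rose from 7.55 ± 0.815 to 11.5 ± 1.81 FPKM and a gene of the heading date repressor family (Solyc03g117670.4) fell from 25.3 ± 3.33 to 17.3 ± 0.296 FPKM. With library totals equalised 7 of the 8 passed adjusted over the list alone; adjusted over all genes LAX3 (-0.40) and Solyc03g117670.4 (-0.23) did not pass.

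Among genes of lists too small to test, both mechanosensitive channel genes rose at 10 days, ERD4 (Solyc08g023440.3) from 56.3 ± 2.19 to 96.9 ± 13.4 FPKM and a Piezo-type gene (Solyc09g074110.4) from 5.95 ± 0.774 to 8.83 ± 1.05 FPKM. Gibberellin 2-oxidase 2 (Solyc07g056670.3) rose from 4.73 ± 1.11 to 9.54 ± 0.391 FPKM and the abscisic acid receptor PYL4 (Solyc03g095780.3) fell by 1.11. The 4 histone genes fell, Solyc09g066100.3 from 120 ± 13.9 to 87.4 ± 9.90 FPKM, but 0 of 4 passed limma with library totals equalised. The 3 ribosomal protein genes fell as well, 0 of 3 with totals equalised, where 60S protein L7a (Solyc06g064460.4) changed from -0.25 to 0.04.

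At 10 days limma called 1111 of 1114 tested genes, 577 higher and 534 lower, 45 of them up and 56 down by at least 1 on the log2 scale; these genes too had been chosen by the authors. The share of called genes that rose was 51.9% as deposited but 77.3% (of 746) with library totals equalised over the table, which moved the median log2 fold change of all genes from 0.35 to 0.62; median ratios gave 0.15 and quantile normalization 0.25.

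The interaction between time and weight was tested in the 371 genes present in both tables and past the low-value filter. The effect differed for 136 of them, 84 with a more positive and 52 with a more negative change at 10 days. Thiamine thiazole synthase (Solyc07g064160.3), of thiamine synthesis, fell at 6 h from 6519 ± 985 to 1527 ± 159 FPKM and rose at 10 days from 3307 ± 571 to 6253 ± 1555 FPKM (difference 2.99, SE 0.26, limma adjusted p = 1.41e-05). The potato inhibitor I gene Solyc09g084460.3 fell at 6 h and rose at 10 days from 45.8 ± 19.4 to 88.3 ± 1.37 FPKM (difference 2.72), as did an uncharacterised gene (Solyc03g093800.1, difference 2.66). GAST1 rose at 6 h from 212 ± 29.1 to 434 ± 40.7 FPKM before its lower value at 10 days (difference -2.86). Snakin-2 rose at 6 h and fell at 10 days from 71.4 ± 12.4 to 44.9 ± 7.37 FPKM (difference -2.63); the fall at 10 days did not pass with library totals equalised (-0.362 instead of -0.653, limma adjusted p = 0.0632). The dioxygenase gene Solyc02g080120.3 rose at both times, by 3.74 at 6 h and 0.90 at 10 days (difference -2.84).

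The photosynthesis list differed between the times by limma and camera, with 5 of 11 genes called, all less negative at 10 days (median difference 0.61, camera adjusted p = 0.0343; adjusted p = 0.585 with an estimated correlation). This call rested on single libraries: without control replicate 1 or 2 at 6 h, weighted replicate 1 or 2 at 6 h, control replicate 1 at 10 days or weighted replicate 2 or 3 at 10 days its adjusted p was 0.0673, 0.0594, 0.0677, 0.0728, 0.0589, 0.0502 and 0.0764. The wound defence list (5 up, 1 down of 8 genes, adjusted p = 0.0872) and the heat shock list (0 of 7 genes, adjusted p = 0.394) did not pass.

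**Figure D5:**
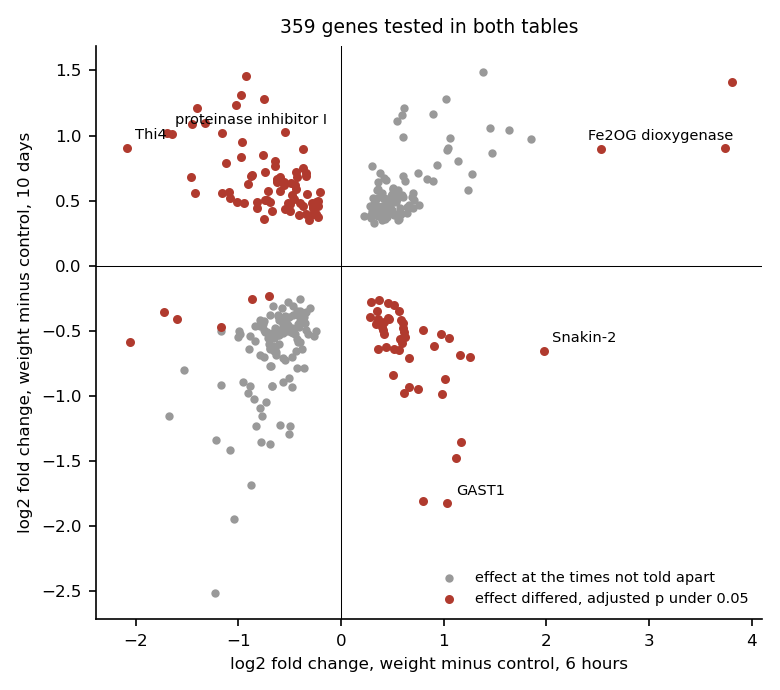
log2 fold change of weighted against control stems at 10 days against that at 6 h for the 359 genes tested in both tables, 1 point per gene, with the 129 of them whose effect differed between the times in red. Of the 359 genes 239 lie in the same direction at both times and 120 in opposite directions; the gap around 0 on each axis comes from the choice of genes.

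Among the 359 genes tested in both, 110 were higher and 129 lower in weighted stems at both times, 45 were higher at 6 h and lower at 10 days, and 75 the reverse. The 66.6% with the same direction compares with 49.8% if the directions at the times were independent. Across these genes, which are not independent replicates, the log2 fold changes correlated with Pearson's r = 0.251 and Spearman's rho = 0.202. All 120 genes with opposite directions were among those whose effect differed, together with 9 of the same direction.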

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

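The test of selection by a threshold in this part was chosen only after the result was seen. The effect of the weight differed between the times for 136 of 371 genes by limma's interaction test. Among the named genes the difference was 2.99 for thiamine thiazole synthase (Solyc07g064160.3), 2.72 for the potato inhibitor I gene Solyc09g084460.3 and 2.66 for Solyc03g093800.1, all lower in weighted stems at 6 h and higher at 10 days. It was -2.86 for GAST1 (Solyc02g089350.3) and -2.63 for Snakin-2 (Solyc01g150176.1), which rose at 6 h and fell at 10 days (for Snakin-2 the fall did not pass with library totals equalised, at -0.362), and -2.84 for the dioxygenase gene Solyc02g080120.3, which rose at both. The photosynthesis list differed by a median of 0.612, its genes falling less at 10 days (camera adjusted p = 0.0343, 0.00238 to 0.0764 over its alternatives; adjusted p = 0.585 with an estimated correlation).

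At least 139 genes were called under each of 3 other scalings, so the count did not rest on the deposited scaling alone. These scalings were computed over the same chosen genes, so they cannot exclude library scaling as a source. A share of 33.4% of the genes tested in both tables lay in opposite directions, but each had been chosen for differing at both times, so a gene of opposite sign differs by that choice. This share therefore does not bear on how far the selection made the differences, which stays open. No biological explanation was tested. Plant age differs between the times and the hour of collection may; neither was tested.

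Of 100 splits of the libraries within each time, 2 gave as many genes, the real one included. The highest other count, 255, came from exchanging control and weighted stems at 10 days, which tests the sum of the effects and so the structure of the groups. Because the genes were chosen on the real split, which favours it, these gene counts do not bear on chance. For lists the real count was 1, 74 of 100 splits gave as many and the highest other was 2. The list count therefore did not set the real split apart.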

How the results depend on the processing

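Alternatives on genes in either table, on the restored decimals, on regrouped genes and without the heat shock list were chosen after seeing the data. Of 3202 values of named genes under alternatives, 3163 kept direction and side of the threshold, 38 kept direction only, and 1 reversed. The reversed one was 60S protein L7a (Solyc06g064460.4) at 10 days, 0.04 with library totals equalised. The named genes had been taken from called genes, mostly by size of change, which favours a high share. With library totals equalised 183 of the 201 named values kept both, and most of the rest were decreases at 10 days.

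Asking for a log2 fold change of at least 1 left 722 of 4995 genes at 6 h and 101 of 1111 at 10 days, by construction. With an estimated correlation camera called 0 lists at 6 h (3 at an unadjusted p under 0.05), 0 at 10 days (0 unadjusted) and 0 for the interaction (0 unadjusted). After quantile normalization camera called 0 lists at 10 days (2 unadjusted); the cause was not tested. With library totals equalised 2 lists differed between the times instead of 1; the cause was not tested. At 5 FPKM or more 5 ethylene, auxin and flowering genes were called at 10 days instead of 8, because fewer were tested. Over genes in either table the interaction was called for 2801 of 5869 genes instead of 136 of 371, so both the count and the share rose. The fold changes correlated at 0.123 instead of 0.251. The added genes had been chosen for differing at a single time, which favours a differing effect and a lower correlation. How much of either change comes from that choice was not tested.

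Leaving out each library gave 4296 to 4700 genes at 6 h, 1056 to 1088 at 10 days and 134 to 142 for the interaction, 8 to 12 lists at 6 h, 2 to 3 at 10 days and 0 to 1 for the interaction, 55 to 64 ethylene, auxin and flowering genes at 6 h, and a correlation of 0.195 to 0.292. The interaction list was lost without 7 of the libraries, given with its values in the report.

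With the replicate block limma called 4555 genes at 6 h and 1110 at 10 days. Deviations of same-numbered libraries correlated at -0.365, -0.29 and -0.04 at 6 h and -0.156, 0.317 and 0.168 at 10 days. At 10 days control replicates 2 and 3 correlated best with the weighted library of their own number, and at 6 h no replicate did. Deviations within a group of 3 depend on each other, so these values do not settle whether same-numbered libraries share a batch. Leaving out the regrouped genes gave 4904 genes at 6 h, restoring possible lost zeros 4995, and leaving out the heat shock list 1098 at 10 days. Methods for counts were planned and not run.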

Other observations

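The tests on the hour of collection and on one control library, and the lists of tubulins and kinesins, glycosyltransferases, pentatricopeptide repeat and all ribosomal proteins, were chosen only after the result was seen, as were the genes named for them. Of 46 tubulin and kinesin genes 39 fell and 7 rose at 6 h (camera adjusted p = 6.45e-05; adjusted p = 0.814 with an estimated correlation), with the tubulin gene Solyc02g087880.3 going from 132 ± 21.6 to 48.7 ± 2.69 FPKM and the kinesin NACK1 (Solyc03g119220.3) from 10.9 ± 1.84 to 4.44 ± 0.211 FPKM. At 10 days all 9 tested genes of that list rose (adjusted p = 0.0404; adjusted p = 0.621 with an estimated correlation), a tubulin beta chain (Solyc03g118760.4) from 10.8 ± 1.67 to 30.3 ± 5.90 FPKM. That call ended without control replicate 1 (adjusted p = 0.0551) and after quantile normalization (0.0573), in a range of 0.0253 to 0.0573. Only 3 genes of the tubulin and kinesin list were tested for the interaction, 1 called and 2 not, at a median difference of -0.023. The counts at the times therefore come mostly from different genes and do not show a reversal. Pentatricopeptide repeat genes went 84 up and 3 down at 6 h (adjusted p = 3.85e-08; adjusted p = 0.814 with an estimated correlation), and all ribosomal protein genes, organellar ones included, 214 up and 26 down (1.12e-12; adjusted p = 0.814 with an estimated correlation). Glycosyltransferases of the UDP-glucosyl family went 4 up and 29 down, with 1 not passing (0.00112; adjusted p = 0.814 with an estimated correlation), Solyc04g008330.1 falling by 1.98. The list of all ribosomal proteins also differed between the times, 7 of 12 more negative and 2 more positive at 10 days (adjusted p = 0.0283, in a range of 0.0184 to 0.055; adjusted p = 0.413 with an estimated correlation), a call that ended without control replicate 1 at 6 h (0.055). Of the 15 added lists 4 passed camera at 6 h, and 1 of the 10 tested at 10 days.

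Genes that rose at 6 h and are not in the 10 day table were higher in weighted stems at 10 days in 1282 of 2073 cases (61.8%), and genes that rose at 10 days and are not in the 6 h table were higher at 6 h in 268 of 371 (72.2%). Tested as sets with the rotation test fry, neither set passed 0.05. Of the genes that fell at 6 h 50.3% of 2212 were higher at 10 days, and of those that fell at 10 days 44% (147 of 334) were higher at 6 h; these sets did not pass 0.05 either.

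Photosynthesis genes fell and clock genes rose at 6 h. At least 49 of 51 photosynthesis genes stayed lower under each of 3 other scalings. This argues against library scaling as the source only as far as scalings over the chosen genes can show. Collection of control and weighted stems at different hours could also give the pattern. Over both times 8 of 9 values of clock genes scored by phase moved as a later hour would move them, 6 of 7 at 6 h and 2 of 2 at 10 days. LHY-like (Solyc10g005080.3), lower at both times, was scored at each, and GIGANTEA (Solyc12g056650.2) was higher at 6 h. The exception was the early gene APRR9 (Solyc03g081240.3), which rose by 0.975 at 6 h. Other called clock genes, such as PRR37 (Solyc04g049670.4, up by 0.621 at 10 days), were not scored. A clock shifted by the load would look alike, and the hours of collection are not given in the sources used here, so these cannot be told apart.

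Heat shock genes were lower in weighted stems at 10 days. At 6 h 28 of the 42 tested genes of the list fell and 14 rose, which did not pass as a list (camera adjusted p = 0.255). Without the control library with the highest values at 10 days the list median was -0.825, so in these genes the fall did not rest on that library alone. The genes had been chosen for differing at 10 days with that library included. That choice favours such an outcome, so it does not exclude the library as a source. The 6 small heat shock protein genes averaged 10.80 ± 0.72 (log2, SD, n = 3) in control and 9.12 ± 0.62 in weighted stems at 10 days, against 5.63 ± 0.12 and 5.00 ± 0.40 at 6 h, so all stems at 10 days were high. Control plants had no clamp, so the weight cannot account for their high level. For the lower level in weighted stems at 10 days, a difference in the temperature felt by the plants may serve as well as a lasting effect of the weight. Neither was tested, and these genes had been chosen for differing at 10 days.

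For splits of 3 libraries against 3 there are 10, too few for a share under 0.05. The genes of each table were chosen on the real split, which favours it, so a high count there does not bear on chance. At 6 h the real split gave 4995 genes and the highest other 0, and 67 ethylene, auxin and flowering genes against 0; 1 of 10 splits reached each. For lists at 6 h 6 of 10 splits reached the real 10 and the highest other was 11. The number of lists past camera with a preset correlation therefore did not set the real split apart at 6 h. At 10 days 1 of 10 splits reached 1111 genes (highest other 16), 3 lists (highest other 2) and 8 ethylene, auxin and flowering genes (highest other 1).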
